A study of Mus musculus with 63 samples.

How the data were processed

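The libraries analysed from C57BL/6 mice were of several kinds, with 24 DNase-seq, 26 RNA-seq and 13 chromatin immunoprecipitation libraries, 63 in all. DNase-seq cuts nuclei with DNase I and sequences the cut ends, so that peaks mark accessible chromatin. Per the labels, nuclei or RNA came from cerebellar cortex at postnatal day 7, 14 or 60 (P7, P14, P60). Cultured granule neurons were taken at 0, 3 or 7 days in vitro (d0, d3, d7), where d0 is the granule neuron precursor fraction of a Percoll gradient from P7 litters. The deposited names of the d3 lists and tables, for DNase and RNA alike, carry 5d, while the titles and sample descriptions give 3 days, which was followed, so the true day of this group is open. Single DNase libraries of adult heart, kidney and liver were the only groups of 1 among the peak lists used. Per the labels, each RNA replicate pooled at least 2 cerebella in vivo and was 1 litter in culture. Each Zic replicate pooled 3 mice at P7 or 2 at P60. RNA fits measure spread between samples, and Fisher's exact tests do not. How H3K27ac replicates were pooled is not given in the sources used.

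The RNA values are FPKM per locus that the authors deposited, 1 file per library. For RNA, DNase and Zic libraries the submitters' processing notes name CASAVA 1.8, BWA (version not given in the sources used here), TopHat2 2.0.8b, Bowtie 1.0.0, MACS 1.4 and Cufflinks 2.0.2, without a role for each. For H3K27ac the submitters' processing notes name CASAVA 1.8, Bowtie 1.0.0 and MACS 1.4. Each DNase list holds exactly 100000 peaks, with a signal per peak that the authors deposited. The DNase peak caller is not given in the sources used here. Each DNase peak also has a score, which the authors deposited and which is capped. Each ChIP list holds the peaks of 1 library with a score per peak, which the authors deposited, from just above 50 upwards. Coordinates are mm9 by the submitters' notes, 1-based. Signals and scores ranked or filtered peaks within lists. The highest DNase signals were compared between lists.

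Most rows of the FPKM files carry an assembled identifier and no symbol, with 7661 to 14131 rows per library naming a gene. A symbol's locus was therefore taken from the rows that pair the locus with the symbol. In each library the row with the same locus gave the value. Otherwise the smallest row that contains the locus was used where the locus spans at least 0.5 of that row, which applied to 1103 to 3321 genes per library. Loci that carry several symbols were left out, loci that share a symbol were summed, and rows with a failed status were dropped (11 to 58 per library). This left 17984 symbols, of which 17850 match a GRCm38.p6 gene table that was used only for names and neighbours, and 68 to 307 were missing in a library. No row names Zic1, Zic4 or Zic5, so a value for Zic1 in every comparison could not be given. Between Tbc1d2b and Plscr5 on chromosome 9 the reference places only Zic1 and Zic4, and 2 recurring loci without a symbol lie there in the files. They are reported by position and neither is assigned a name. Values of exactly 0 occurred for genes that other libraries hold at high levels, so such genes are described only as listed at 0. Overlapping genes cannot be told apart where the assembled row spans both.

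Depth was read from the upper confidence bound that the files give beside each FPKM, taken as the value plus 2 Poisson standard deviations. The bounds imply 21.7 to 50.5 M (1e6) fragments per RNA library, as an approximation, since 77.8% to 81.5% of low rows came out within 0.02 of a whole number. The depth of DNase and ChIP libraries is unknown, because peak lists give no read totals, and the fixed list length keeps the number of DNase peaks from reflecting accessibility.

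Changes were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend) on log2(FPKM + 1), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on that scale, which understates the change of low genes. Genes needed at least 1 FPKM in as many libraries as the smallest group of the fit. Separate fits were made over the 9 cerebellum, 11 culture and 6 knockdown libraries, each sharing 1 estimate of the spread. An interaction fit over 12 libraries tested whether the change from P7 to P60 differed from that between d0 and d7. SD is the spread between libraries and SE is the standard error of the log2 change. Genes tested numbered 9003, 9099, 8685 and 9181 in these fits.

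The 20 gene lists were written from general knowledge: cell cycle, Sonic hedgehog pathway and granule neuron precursors, neuronal migration and axon growth, mature granule neuron, synaptic vesicle and synapse, voltage-gated channels, immediate early and activity-regulated genes, Zic family, chromatin regulators, markers of Purkinje cells, interneurons and unipolar brush cells, astrocytes and Bergmann glia, oligodendrocytes, their precursors, microglia, endothelium, fibroblasts with meninges and pericytes, erythroid cells, and the interferon and p53 responses. They hold 333 genes, of which 263 have a named value. Lists with at least 3 measured members were tested against all other genes by camera with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists. The Zic family and erythroid lists, with 2 measured members each, were not tested as lists. Samples, groups, tests, the alternatives listed below and the rule for named genes were fixed before the data were examined.

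The named-gene rule took, for P60 against P7, d7 against d0, BDNF and both knockdowns, the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 5 FPKM in the higher group and no overlap between the groups' libraries. For other comparisons it took 3 each way. Symbols of predicted genes, microRNAs and small nucleolar RNAs were skipped. From each list it took up to 4 members that passed, or else up to 2 as values, and Zic1 and Zic2 everywhere. Some genes that this rule took are not reported here. For each class the 3 regions with the best mean rank by the authors' score were taken with the nearest gene, and not all are reported.

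Peaks of a comparison were merged into regions with a minimum overlap of 1 bp, and a region was counted as specific to a group when every library of that group and no library of the other had a peak in it. Regions were tied to genes within 100 kb. Lists were compared by Jaccard index with exact permutation of the labels, and counts by Fisher's exact test, two-sided, in Python 3.11.15 (numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1). Region and gene counts are not independent replicates. Tissue shares have exact Clopper-Pearson 95% intervals, which cover counting error only. With 3 libraries against 3 an exact permutation cannot give a p below 0.1, and with 2 against 2 none below 0.33.

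Groups carry the same replicate numbers, and the labels do not state that a number marks a shared litter or day. Among comparisons of 3 libraries with 3, deviations from the group means correlated above 0.1 for every number only for d3 and d0 (0.128, 0.116 and 0.203), which meets the bar set for pairing from the data; the main fit, fixed before the data were seen, holds no block. They also did for the Zic1 knockdown with its control (0.197), the Zic2 knockdown with its control (0.156) and the knockdowns with each other (0.389), where 2 libraries per group give the same value for both numbers. With 2 pairs this does not settle pairing, and counts with the block stand beside those without it. For d3 against d0 a block for the replicate number called 2785 genes, against 2747 without it.

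The RNA test was tested on simulated data with 200 changed genes in each comparison. It recovered 83% of log2 changes of 1 and 95% of 2 for P60 against P7 over 9003 genes, and 28% and 81% for d7 against d0 over 9099 genes. For BDNF it recovered 22% and 75% over 9099 genes. Over 8685 genes it recovered 0% at either size for each knockdown against control, and 0% and 32% between the knockdowns, so 2 libraries against 2 detect little. False calls were 7.8% of calls for P60 against P7, 5.9% for P60 against P14, 9.9% for d7 against d3 and 0% to 4.9% elsewhere. For the interaction it recovered 15% and 61% over 9181 genes. In 3873 simulated regions it found 504, 303 and 2700 where 500, 300 and 2700 had been planted.

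The alternatives were a pseudocount of 0.1, no filter, quantile normalization, leaving out each replicate in turn, the replicate block, a fit of the compared groups only, the better-scoring part of each peak list, 50% coverage for shared peaks, and regions that overlap the gene locus only. The P7 and P60 input and IgG libraries and the P60 cortex Zic library were not analysed here.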

Results

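Chromatin accessibility, transcripts and Zic binding were measured in the developing mouse cerebellum and in granule neurons cultured from it. Granule neurons are the small excitatory neurons of the cerebellar cortex, and they arise after birth from dividing precursors that respond to Sonic hedgehog. Zic1 and Zic2 are zinc finger transcription factors made in this lineage. RNA and DNase libraries numbered 3 each for P7, P14 and P60 cerebellum (postnatal days) and for cultures at d0, d3 and d7 (days in vitro), where d0 is the precursor fraction isolated from P7 litters. The day of the d3 group is not certain, as its deposited names carry 5d and its descriptions 3 days. Cultures at d7 that received 50 ng/mL of the neurotrophin BDNF at day 4 had 2 RNA and 3 DNase libraries. RNA from d7 cultures with lentiviral short hairpin RNA against Zic1, against Zic2 or with a control virus had 2 libraries each. Binding of Zic (an antibody to the C-terminus of Zic1 and Zic2) and acetylation of histone H3 at lysine 27 (H3K27ac, found at active enhancers and promoters) were mapped at P7 and P60 with 2 libraries each. RNA depth was about 21.7 to 50.5 M fragments per library, and every DNase library was deposited as 100000 peaks. FPKM values are means ± SD over libraries, and changes are log2(FPKM + 1) with their SE.

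The comparison of P60 with P7 asked which genes the cerebellum turns up and down as it matures. Cbln3, a granule neuron partner of the synapse organizer cerebellin 1 (chromosome 14, 56497757 to 56503093), rose from 6.80 ± 2.07 to 333 ± 34.0 FPKM (n = 3 each), which is 5.45 (SE 0.20, adjusted p = 3.43e-08). Fam107a, an actin-associated protein (chromosome 14, 9128792 to 9142290), rose from 3.57 ± 1.38 to 289 ± 61.7 FPKM (6.02, SE 0.28, adjusted p = 1.36e-07). Other large rises were Dao (D-amino acid oxidase, 5.22), Gpd1 (glycerol-3-phosphate dehydrogenase, 4.70) and the potassium channel subunit Kcng4 (4.64). The G protein subunit gene Gng13 was listed at 0, 17.7 and 24.5 FPKM at P7 and at 844, 477 and 650.2 at P60 (adjusted p = 0.000424). Tnfrsf12a was listed at 0 in all P7 libraries and at 34.2, 23.0 and 24.1 at P60. Large falls included Igfbpl1 (chromosome 4, 45822379 to 45839699), from 169 ± 35.5 to 0.0810 ± 0.0378 FPKM (−7.28, SE 0.19). Insm1, a transcription factor of neuronal progenitors, fell from 106 ± 3.00 to 0.0930 ± 0.0230 (−6.61, SE 0.13). Mfap4 (−6.33), the topoisomerase Top2a (−6.21), the growth cone protein Basp1 (−6.06), the mitotic kinase Cdk1 (−5.75) and the proliferation marker Mki67 (−5.50) also fell.

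All 26 measured cell cycle genes fell, 26 adjusted over the list alone, with a median of −3.89 (camera adjusted p = 6.64e-13, adjusted p = 0.0913 with an estimated correlation). Ccnb1 (cyclin B1) fell from 40.9 ± 2.20 to 0.165 ± 0.0653 FPKM. Of 18 genes of the Sonic hedgehog pathway and granule neuron precursors 16 fell, 16 adjusted over the list alone (adjusted p = 2.37e-07, adjusted p = 0.0534 with an estimated correlation). Among them were the neuronal factor Nhlh1 (−5.41) and cyclin D2, Ccnd2 (−4.87). For neuronal migration and axon growth 13 of 16 fell and 1 rose, 14 adjusted over the list alone (adjusted p = 0.000845, adjusted p = 0.0774 with an estimated correlation). Dpysl3 fell from 111 ± 9.80 to 3.43 ± 0.174 FPKM, the chemokine receptor Cxcr4 by 3.75 and the tubulin Tubb2b by 3.21. Of 17 mature granule neuron genes 15 rose and 1 fell, 16 adjusted over the list alone (adjusted p = 4.15e-08, adjusted p = 0.0774 with an estimated correlation). Gabrd, the GABA-A receptor delta subunit, rose from 9.22 ± 4.76 to 119 ± 12.8 FPKM and the signalling gene Chn2 by 3.37. Of 16 synapse genes 14 rose and 1 fell, 15 adjusted over the list alone (adjusted p = 2.59e-06, adjusted p = 0.161 with an estimated correlation). Vamp1, a synaptic vesicle fusion protein, rose from 14.7 ± 2.69 to 107 ± 16.6 FPKM, while the member that fell was Stx1a, the fusion protein syntaxin 1A, from 30.6 ± 5.49 to 1.22 ± 0.0547 (−3.81). All 11 voltage-gated channel genes rose, 11 adjusted over the list alone (adjusted p = 4.38e-07, adjusted p = 0.0913 with an estimated correlation). Sodium channel subunit Scn4b rose by 3.99 and the potassium channel partner Kcnip4 by 3.60.

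Among immediate early and activity-regulated genes 10 of 20 rose and 4 fell, 14 adjusted over the list alone (adjusted p = 0.0345, adjusted p = 0.528 with an estimated correlation). The synaptic pentraxin Nptx1 rose from 10.3 ± 3.19 to 170 ± 24.6 FPKM, Bdnf from 0.366 ± 0.0490 to 3.87 ± 0.263 and Arc from 1.41 ± 0.470 to 6.65 ± 0.827. Of 11 chromatin regulators 10 fell, 10 adjusted over the list alone (adjusted p = 0.00917, adjusted p = 0.208 with an estimated correlation). Uhrf1, which maintains DNA methylation in dividing cells (−4.97), and Hmgb2 (−4.62) were among them. Zic2 fell from 148 ± 16.5 to 91.6 ± 11.4 FPKM (−0.69, SE 0.12, adjusted p = 0.000938).

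Purkinje cell markers rose for 8 of 11 genes and fell for 1, 9 adjusted over the list alone, and were called as a list (adjusted p = 0.00104, adjusted p = 0.0913 with an estimated correlation). The calcium channel gene Itpr1 rose from 52.4 ± 7.32 to 363 ± 45.7 FPKM. Interneuron and unipolar brush cell markers rose for 7 of 10 and fell for 2, 9 adjusted over the list alone (adjusted p = 0.017, adjusted p = 0.222 with an estimated correlation). Of 13 oligodendrocyte markers 12 rose, 12 adjusted over the list alone (adjusted p = 2.59e-06, adjusted p = 0.142 with an estimated correlation), including the myelin genes Opalin (3.56) and Mobp (2.87). All 8 oligodendrocyte precursor markers fell, 8 adjusted over the list alone, with Gpr17 at −2.65 and the receptor Pdgfra at −2.31 (adjusted p = 0.00438, adjusted p = 0.0913 with an estimated correlation). Astrocyte and Bergmann glia markers were split, with 6 rising and 6 falling, 12 adjusted over the list alone (list adjusted p = 0.71, median 0.01, mean −0.15 and test upwards). S100b rose from 36.7 ± 4.94 to 340 ± 19.4 FPKM, while the radial glia gene Fabp7 fell from 1433 ± 136 to 115 ± 12.4 and Gfap from 221 ± 45.1 to 60.5 ± 1.29. Lists not called were microglia (10 of 13 fell and 2 rose, 12 adjusted over the list alone, adjusted p = 0.126) and fibroblasts, meninges and pericytes (5 of 9 fell and 1 rose, against 3 and 1 under quantile normalization, 6 adjusted over the list alone, adjusted p = 0.195). The same held for the interferon response (1 of 6 rose and 1 fell, against 4 and 0 under quantile normalization, 2 adjusted over the list alone, adjusted p = 0.423) and the p53 response (5 of 9 fell and 2 rose, 7 adjusted over the list alone, adjusted p = 0.715). For the endothelium 3 of 9 rose and 3 fell, 6 adjusted over the list alone (adjusted p = 0.842). The endothelial median of −0.23 differed in sign from the mean of 0.07 and the upward test, and became 0.08 under quantile normalization. Of the pair of measured erythroid genes, the haemoglobin gene Beta-s (−1.18) and the haem synthesis gene Alas2 (−0.73) fell.

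In all, 5767 of 9003 genes passed limma's test at P60 against P7, 2151 rising and 3616 falling. Quantile normalization, which moved the median of all genes from −0.18 to 0.02, gave 2939 rising and 2844 falling, so that 50.8% of calls rose against 37.3%. Over all comparisons 6 of 85 list calls held with an estimated correlation. They were the Sonic hedgehog and precursor list at P14 against P7, P60 against P14, d7 against d0 and d3 against d0, the migration list at P60 against P14, and the immediate early list in the difference between tissue and culture.

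**Figure D1:**
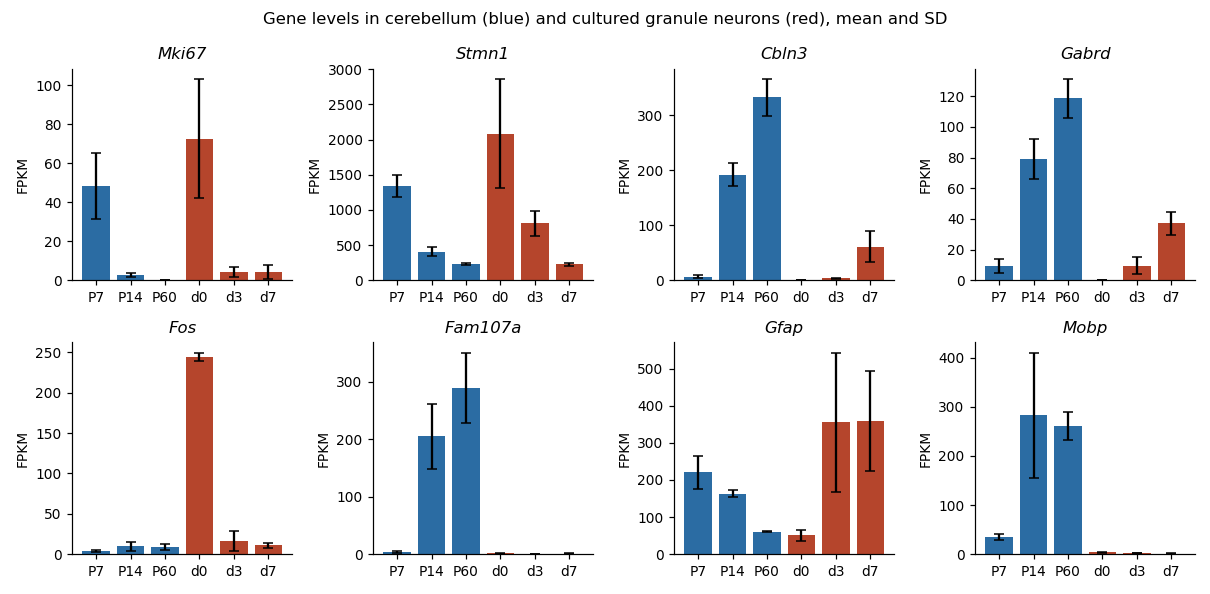
FPKM of 8 genes (bars, mean; lines, SD, n = 3 libraries) at P7, P14 and P60 in cerebellum (blue) and d0, d3 and d7 in culture (red). Cbln3 rose from 6.80 to 333 FPKM in cerebellum and from 0.840 to 60.6 in culture, while Fos fell from 245 to 10.9 in culture and rose from 3.77 to 9.36 in cerebellum.

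The steps from P7 to P14 and from P14 to P60 divided this change over age. By P14 Fam107a had reached 205 ± 56.2 FPKM (5.51, adjusted p = 6.98e-07), Cbln3 192 ± 20.7 (4.66) and the glutamate transporter Slc17a7 222 ± 28.9 (2.83). The myelin gene Mal rose from 4.60 ± 0.699 to 143 ± 24.4 FPKM (4.68). All 13 oligodendrocyte markers rose, 13 adjusted over the list alone (adjusted p = 5.63e-10, adjusted p = 0.0749 with an estimated correlation), with the myelin gene Mog from 10.2 ± 1.49 to 118 ± 17.9 FPKM. All 26 cell cycle genes fell, 26 adjusted over the list alone, with Cdk1 at −3.91 (adjusted p = 4.41e-16, adjusted p = 0.0749 with an estimated correlation). The precursor list fell for 16 of 18, 16 adjusted over the list alone (adjusted p = 5.79e-08, adjusted p = 0.045 with an estimated correlation). Atoh1, the transcription factor of granule neuron precursors, fell from 10.5 ± 0.797 to 0.757 ± 0.102 FPKM. Mature granule neuron genes rose for 15 of 17 and fell for 1 (16 adjusted over the list alone, adjusted p = 7.68e-10, adjusted p = 0.0749 with an estimated correlation). Synapse genes rose for 15 of 16 with 1 fall (16 adjusted over the list alone, adjusted p = 6.39e-07, adjusted p = 0.152 with an estimated correlation). Channel genes rose for 9 of 11 (9 adjusted over the list alone, adjusted p = 1.26e-06, adjusted p = 0.0749 with an estimated correlation). Purkinje markers rose for 9 of 11 and fell for 1 (10 adjusted over the list alone, adjusted p = 0.000343, adjusted p = 0.0749 with an estimated correlation). Migration genes fell for 10 of 16 (11 adjusted over the list alone, adjusted p = 0.0295, adjusted p = 0.126 with an estimated correlation). Immediate early genes rose for 7 of 20 and fell for 2, against 13 and 2 under quantile normalization (8 adjusted over the list alone, adjusted p = 0.00879, adjusted p = 0.343 with an estimated correlation). Chromatin regulators fell for 7 of 11 (7 adjusted over the list alone, adjusted p = 0.0295, adjusted p = 0.296 with an estimated correlation). Interneuron markers rose for 6 of 10 and fell for 1 (7 adjusted over the list alone, adjusted p = 0.0399, adjusted p = 0.296 with an estimated correlation). Zic2 was at 131 ± 4.15 FPKM at P14, a difference of −0.17 from P7 that did not pass (adjusted p = 0.27). In all 4639 genes passed, 1831 up and 2808 down. Quantile normalization moved the median of all genes from −0.11 to 0.00 and gave 2372 up and 2325 down (50.5% up against 39.5%).

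From P14 to P60 the precursor list fell again for 14 of 18 genes, 11 under quantile normalization, and rose for 1 (15 adjusted over the list alone, adjusted p = 6.15e-06, adjusted p = 0.0435 with an estimated correlation). Migration and axon genes fell for 12 of 16 (12 adjusted over the list alone, adjusted p = 2.66e-05, adjusted p = 0.0435 with an estimated correlation). Basp1 fell from 112 ± 12.8 to 5.24 ± 0.493 FPKM (−4.17, SE 0.11, n = 3 each, adjusted p = 1.26e-07). Oligodendrocyte markers, which had risen by P14, fell for 7 of 13 and rose for 1 (9 adjusted over the list alone, median −1.06, adjusted p = 0.0198, adjusted p = 0.439 with an estimated correlation). The myelin basic protein gene Mbp fell from 2781 ± 520.4 to 1111 ± 73.1 FPKM and the lipid enzyme gene Ugt8a by 1.83. Precursors of that lineage fell for 7 of 8 markers (7 adjusted over the list alone, adjusted p = 0.000419, adjusted p = 0.0871 with an estimated correlation). Cell cycle genes fell for 22 of 26, and for 18 under quantile normalization (23 adjusted over the list alone, adjusted p = 2.8e-11, adjusted p = 0.192 with an estimated correlation). Channel genes rose for 7 of 11 and fell for 1 (8 adjusted over the list alone, adjusted p = 0.000419, adjusted p = 0.229 with an estimated correlation). Mature granule neuron genes rose for 6 of 17 and fell for 1 (8 adjusted over the list alone, adjusted p = 0.00639, adjusted p = 0.316 with an estimated correlation). Interneuron markers rose for 3 of 10 (3 adjusted over the list alone, adjusted p = 0.0441, adjusted p = 0.378 with an estimated correlation). Cbln3 rose by a further 0.79 and Bdnf by 1.11. The Bergmann glia gene Gdf10 fell from 206 ± 19.9 to 81.1 ± 12.9 FPKM and Zic2 fell by 0.51 (adjusted p = 0.0134). Fdft1, an enzyme of cholesterol synthesis, was listed at 27.1, 31.1 and 30.8 FPKM at P14 and at 0 in all P60 libraries. In all 2593 genes passed, 870 up and 1723 down, and 1235 up and 1261 down under quantile normalization (49.5% up against 33.6%).

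**Figure D2:**
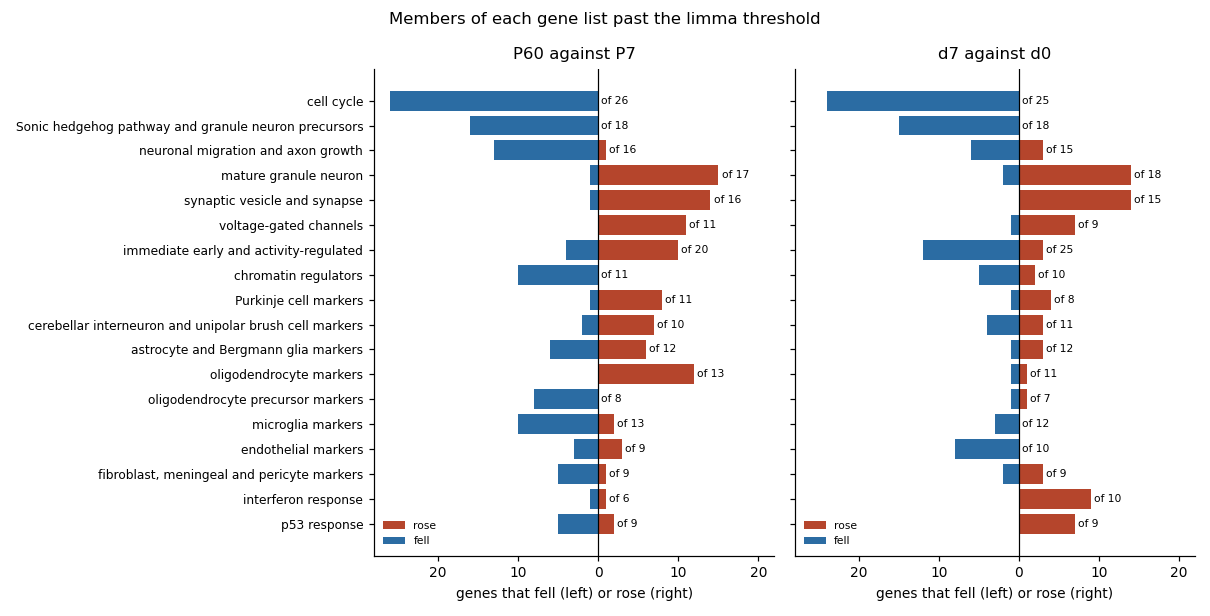
Number of measured genes that rose (right) or fell (left) in each of 18 lists for P60 against P7 and d7 against d0, limma adjusted p under 0.05. All 26 cell cycle genes fell in cerebellum and 24 of 25 in culture, while immediate early genes split as 10 up and 4 down in cerebellum and 3 up and 12 down in culture.

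The comparison of d7 with d0 followed the same lineage outside the tissue. The calcium sensor gene Vsnl1 rose from 1.35 ± 0.472 to 116 ± 34.2 FPKM (5.62, SE 0.23, n = 3 each, adjusted p = 2.97e-07), Phyhip by 5.82 and the vesicle protein gene Rph3a by 5.28. The interferon-induced gene Ifitm3 rose from 13.0 ± 7.68 to 644 ± 302 FPKM (5.56) and the acute phase gene Saa3 from 0.354 ± 0.111 to 342 ± 200.4 (7.81, SE 1.45). The smooth muscle gene Tagln was listed at 0 in all d0 libraries and at 94.6, 88.3 and 484 FPKM at d7. Large falls included Beta-s, from 153 ± 39.4 to 0.156 ± 0.105 FPKM (−7.03), and the endothelial junction gene Cldn5, from 112 ± 79.3 to 0.168 ± 0.0619 (−6.34). Fdft1 and Pold2 were listed at 0 in all d7 libraries, against 42.2, 78.7 and 92.7 FPKM and 44.8, 46.7 and 33.0 at d0.

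Of 18 precursor genes 15 fell, 16 adjusted over the list alone (adjusted p = 4.72e-11, adjusted p = 0.00253 with an estimated correlation). The Sonic hedgehog effector Gli1 fell from 25.9 ± 1.31 to 0.0737 ± 0.0584 FPKM, Insm1 by 4.60 and the Wnt modulator Sfrp1 by 3.97. Of 25 cell cycle genes 24 fell, 24 adjusted over the list alone, among them Mki67 from 72.6 ± 30.7 to 4.14 ± 3.58 FPKM (adjusted p = 4.72e-11, adjusted p = 0.375 with an estimated correlation). Mature granule neuron genes rose for 14 of 18 and fell for 2, 16 adjusted over the list alone (adjusted p = 5.4e-07, adjusted p = 0.375 with an estimated correlation). Chn2 rose from 3.15 ± 0.442 to 141 ± 42.3 FPKM (5.06) and Cbln3 by 4.97. Synapse genes rose for 14 of 15, 14 adjusted over the list alone, with the vesicle gene Syn2 from 13.9 ± 1.99 to 171 ± 80.6 FPKM (adjusted p = 1.39e-05, adjusted p = 0.375 with an estimated correlation). Channel genes rose for 7 of 9 with 1 fall, 8 adjusted over the list alone, with the potassium channel gene Kcna1 at 2.75 (adjusted p = 0.00395, adjusted p = 0.375 with an estimated correlation). Immediate early genes fell for 12 of 25, 15 under quantile normalization, and rose for 3, 17 adjusted over the list alone (adjusted p = 0.00126, adjusted p = 0.384 with an estimated correlation). Fos fell from 245 ± 5.19 to 10.9 ± 2.64 FPKM (−4.40), whereas Nptx1 rose from 1.41 ± 0.392 to 91.2 ± 35.2. Endothelial markers fell for 8 of 10, 8 adjusted over the list alone, with the receptor Kdr at −3.55 (adjusted p = 3.26e-05, adjusted p = 0.375 with an estimated correlation). Interferon response genes rose for 9 of 10, 9 adjusted over the list alone, with Ifit3 from 0.320 ± 0.171 to 42.8 ± 35.8 FPKM (adjusted p = 0.000337, adjusted p = 0.384 with an estimated correlation). Genes of the p53 response rose for 7 of 9, 7 adjusted over the list alone, with Phlda3 at 4.13 and Cdkn1a, the cell cycle inhibitor p21, at 2.56 (adjusted p = 0.00382, adjusted p = 0.375 with an estimated correlation).

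Other lists were not called at d7 against d0. Migration genes fell for 6 of 15 and rose for 3, against 1 rising under quantile normalization (9 adjusted over the list alone, adjusted p = 0.0954), with Stmn1, a microtubule regulator, at −3.16 and Tubb3 at −2.82. Among glia, Gfap rose from 50.5 ± 14.1 to 359 ± 136 FPKM and Gdf10 fell by 4.36 (astrocyte list 3 up and 1 down of 12, 4 adjusted over the list alone, adjusted p = 0.708). Trf rose by 1.68 and Mobp fell from 4.05 ± 1.04 to 0.917 ± 1.01 FPKM (oligodendrocytes, 1 up and 1 down of 11, 2 adjusted over the list alone, adjusted p = 0.677). The microglial receptor Csf1r fell by 1.89 (3 down of 12, 3 adjusted over the list alone, adjusted p = 0.623). Fibroblast-type genes rose for 3 of 9 and fell for 2 (5 adjusted over the list alone, adjusted p = 0.709), with the collagen gene Col1a2 from 51.6 ± 47.2 to 319 ± 324 FPKM and the pericyte gene Rgs5 at −2.32. The Purkinje list (4 up and 1 down of 8, 5 adjusted over the list alone, adjusted p = 0.565) held Pcp4 at 4.11 and Grid2ip at −3.76. Interneuron genes (3 up and 4 down of 11, 7 adjusted over the list alone, adjusted p = 0.754) were not called, nor were chromatin regulators (2 up and 5 down of 10, 8 adjusted over the list alone, adjusted p = 0.126) and oligodendrocyte precursor markers (1 up and 1 down of 7, 2 adjusted over the list alone, adjusted p = 0.709). The oligodendrocyte precursor list had a median of −0.21 and a mean of 0.03 with a downward test, and microglia a median of 0.16 and a mean of −0.17 with a downward test. Zic2 was at 184 FPKM at d7 and 207 ± 43.6 at d0, a difference of −0.20 (SE 0.26) that did not pass (adjusted p = 0.575). In all 3831 of 9099 genes passed, 2090 up and 1741 down, and under quantile normalization the majority turned, with 1862 up and 2038 down. Libraries d0 1, d3 3 and d7 3 stood apart from their groups, with an SD of deviations over genes of 0.559, 0.517 and 0.560 against 0.257 to 0.453 in the other culture libraries.

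Against d0, at d3 precursor genes fell for 16 of 18 (18 adjusted over the list alone, adjusted p = 4.86e-11, adjusted p = 0.00254 with an estimated correlation), with Atoh1 from 15.0 ± 1.91 to 0.255 ± 0.0895 FPKM. Cell cycle genes fell for 23 of 25 (24 adjusted over the list alone, adjusted p = 1.34e-11, adjusted p = 0.417 with an estimated correlation). All 15 synapse genes rose (15 adjusted over the list alone, adjusted p = 9.56e-08, adjusted p = 0.417 with an estimated correlation). Mature granule neuron genes rose for 11 of 18 and fell for 3 (14 adjusted over the list alone, adjusted p = 0.00061, adjusted p = 0.549 with an estimated correlation). Channel genes rose for 5 of 9 (6 adjusted over the list alone, adjusted p = 0.0052, adjusted p = 0.417 with an estimated correlation). Immediate early genes fell for 15 of 25 and rose for 2 (19 adjusted over the list alone, adjusted p = 0.000162, adjusted p = 0.46 with an estimated correlation). Fosb fell from 73.6 ± 27.3 to 0.126 ± 0.0381 FPKM and the transcription factor Egr1 by 3.93. Endothelial markers fell for 9 of 10 (9 adjusted over the list alone, adjusted p = 4.03e-07, adjusted p = 0.197 with an estimated correlation). Pcp4 rose from 20.7 ± 11.7 to 862 ± 129 FPKM and Mfap4 fell from 315 ± 87.6 to 3.51 ± 1.71, while Zic2 was at 192 ± 20.0 (−0.09, adjusted p = 0.812). In all 2747 genes passed, 1242 up and 1505 down, and 714 of the genes with the same span in every library did. The majority turned without d3 library 3 (1272 up and 1199 down) and with the 3 libraries that stood apart left out (2069 up and 1857 down).

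Between d3 and d7 the mature granule neuron genes rose for 10 of 18 (11 adjusted over the list alone, median 1.33, adjusted p = 3.7e-09, adjusted p = 0.298 with an estimated correlation). They included Cbln3, from 3.24 ± 0.929 to 60.6 ± 28.1 FPKM (n = 3 each), and Slc17a7, from 5.72 ± 2.18 to 85.5 ± 43.3. Migration and axon genes fell for 8 of 15 (10 adjusted over the list alone, adjusted p = 1.53e-08, adjusted p = 0.0707 with an estimated correlation), with Tubb3 from 228 ± 35.0 to 57.0 ± 18.8 FPKM and Dpysl5 at −1.87. Precursor genes fell for 6 of 18 and rose for 1, Ccnd1 at 2.46 (9 adjusted over the list alone, adjusted p = 0.000142, adjusted p = 0.0536 with an estimated correlation). Interferon genes rose for 7 of 10, and for 3 under quantile normalization (10 adjusted over the list alone, adjusted p = 1.46e-07, adjusted p = 0.298 with an estimated correlation), with Bst2 from 14.4 ± 8.07 to 116 ± 65.1 FPKM. Fibroblast-type genes rose for 2 of 9 (7 adjusted over the list alone, adjusted p = 0.000141, adjusted p = 0.32 with an estimated correlation). The p53 list rose for 1 of 9, Eda2r at 1.87, and for 2 under quantile normalization (7 adjusted over the list alone, adjusted p = 0.00204, adjusted p = 0.32 with an estimated correlation). Egr1 rose by 2.70 and Zic2 differed by −0.10 (adjusted p = 0.908). In all 509 genes passed, 367 up and 142 down. Quantile normalization moved the median of all genes from 0.07 to −0.07 and gave 276 up and 200 down (58.0% up against 72.1%). This count was 254 without d3 library 1, 223 without d3 library 2 and 289 without d7 library 1. Ccnd1, Bst2 and Eda2r did not pass without d3 library 1, nor with only these 2 groups in the fit. The count was 202 with only these 2 groups in the fit, 127 among genes of the same span, and 1513 with the 3 libraries that stood apart left out together, where the majority turned to 728 up and 785 down (48.1% up).

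Changes in tissue and culture were set side by side over 8319 genes measured in both. The changes from P7 to P60 and from d0 to d7 had a Pearson correlation across genes of 0.56 (Spearman 0.527), and genes are not independent replicates. Of 2605 genes called in both, 981 rose and 1264 fell in both (421 and 667 if the lists were independent), and 360 moved in opposite directions, 100 of them rising in tissue. Quantile normalization gave 179 and 158 for the opposite genes. The test of the difference between the changes called 2296 of 9181 genes. The change was higher in tissue for 745 and lower for 1551. Quantile normalization, which moved the median of all genes from −0.24 to 0.04, gave 1314 and 1096 (54.5% higher against 32.4%).

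Immediate early genes differed between tissue and culture, with 15 of 24 higher in tissue and 4 lower, against 16 and 1 under quantile normalization, 20 adjusted over the list alone (median 1.43, adjusted p = 1.24e-08, adjusted p = 0.0107 with an estimated correlation). Fos rose from 3.77 ± 0.814 to 9.36 ± 3.65 FPKM in tissue and fell from 245 ± 5.19 to 10.9 ± 2.64 in culture, a difference of 5.47 (SE 0.37, n = 3 each, adjusted p = 3.60e-06). Arc rose by 1.68 in tissue and fell by 1.06 in culture. Other genes that rose in tissue and fell in culture were Sept4, a septin, with a difference of 5.30, and the carbonic anhydrase gene Car4 with 5.17. Changes of oligodendrocyte markers were higher in tissue for 7 of 14 (8 adjusted over the list alone, adjusted p = 3.56e-07, adjusted p = 0.1 with an estimated correlation). Endothelial markers were higher for 7 of 9 (7 adjusted over the list alone, adjusted p = 3.8e-07, adjusted p = 0.0912 with an estimated correlation), and Purkinje markers for 5 of 10 with 1 lower (8 adjusted over the list alone, adjusted p = 0.0204, adjusted p = 0.0912 with an estimated correlation). The differences lay towards culture for the p53 response (7 of 9, 8 adjusted over the list alone, adjusted p = 0.000241, adjusted p = 0.0912 with an estimated correlation) and interferon genes (8 of 9, 9 adjusted over the list alone, adjusted p = 0.000412, adjusted p = 0.451 with an estimated correlation). So did those of oligodendrocyte precursor markers (5 of 7, and 3 under quantile normalization, 5 adjusted over the list alone, adjusted p = 0.0204, adjusted p = 0.0912 with an estimated correlation). Changes of cell cycle genes were lower in tissue for 8 of 25 (8 adjusted over the list alone, adjusted p = 0.0246, adjusted p = 0.748 with an estimated correlation). The channel list was higher for 4 of 10 and lower for 1 (5 adjusted over the list alone, adjusted p = 0.0246, adjusted p = 0.455 with an estimated correlation). That list had a median of 0.00, a mean of 0.73 and a median of 0.29 under quantile normalization. Saa3 (−7.63), the iron-binding gene Lcn2 (−6.69) and the protease inhibitor gene Timp1 (−5.89) had large differences towards culture.

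**Figure D3:**
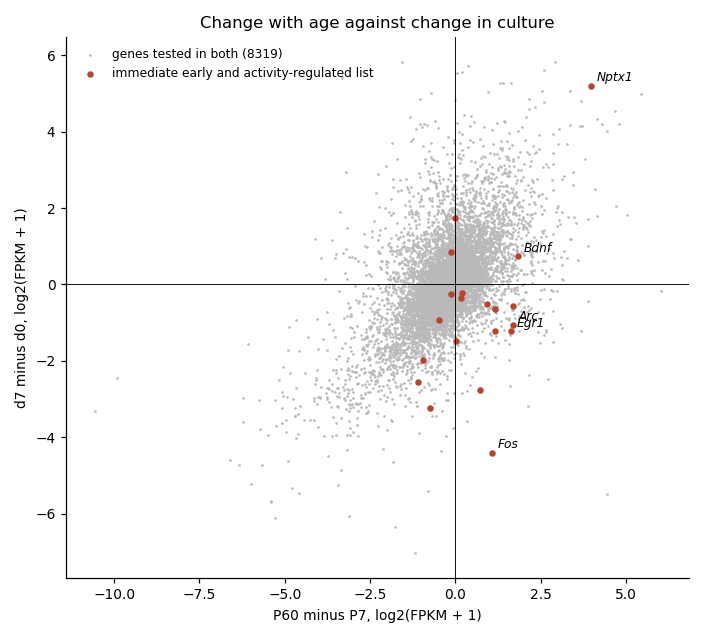
Change from d0 to d7 in culture against change from P7 to P60 in cerebellum for 8319 genes (points, log2 scale; Pearson correlation 0.56), with the immediate early list in red. Fos lies at 1.07 in cerebellum and −4.40 in culture, and Nptx1 at 3.96 and 5.20.

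BDNF, a neurotrophin that acts through the receptor TrkB, was compared with untreated d7 cultures. The neuropeptide gene Nts rose from 0.401 ± 0.229 (n = 3) to 26.2 ± 5.27 FPKM (n = 2), a change of 4.28 (SE 0.20, adjusted p = 4.92e-06). Rises also reached the collagen gene Col28a1 (3.99), Car4 from 1.02 ± 0.487 to 27.8 ± 12.6 (3.79) and Galnt14 (3.21). Kcnip4 rose from 1.07 ± 0.441 to 17.2 ± 1.37 FPKM (3.15). The neurofilament gene Nefh was listed at 0 in all d7 libraries and at 17.4 and 24.2 FPKM with BDNF. Falls included the Wnt inhibitor gene Nkd1 from 21.8 ± 8.25 to 2.68 ± 0.0191 (−2.57), Ramp3 (−2.19), the transcriptional inhibitor Id2 from 124 ± 5.96 to 28.3 ± 0.683 (−2.09, adjusted p = 0.0287) and Stx1a from 18.3 ± 4.47 to 4.51 ± 0.0179 (−1.78). Il34 and Thtpa were listed at 0 in both BDNF libraries, against 10.3, 8.46 and 15.3 FPKM and 11.4, 11.2 and 10.9 at d7.

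Oligodendrocyte markers rose with BDNF for 2 of 11, and for 5 under quantile normalization (7 adjusted over the list alone, median 1.57, adjusted p = 9.85e-09, adjusted p = 0.312 with an estimated correlation). Ugt8a rose from 1.19 ± 0.431 to 7.67 ± 1.44 FPKM. Mature granule neuron genes rose for 2 of 18 (4 adjusted over the list alone, adjusted p = 0.00704), channel genes for 2 of 9 (3 adjusted over the list alone, adjusted p = 0.00546), and interneuron genes for 1 of 11, the glycine transporter Slc6a5 at 2.12 (5 adjusted over the list alone, adjusted p = 0.0411), each with adjusted p = 0.803 with an estimated correlation. None of 25 immediate early genes passed, against 3 rising under quantile normalization (1 adjusted over the list alone, list upwards with adjusted p = 0.00132, adjusted p = 0.803 with an estimated correlation). Nor did any of 25 cell cycle genes (0 adjusted over the list alone, list downwards with adjusted p = 7.18e-05, adjusted p = 0.803 with an estimated correlation). Spry4, an inhibitor of receptor kinase signalling, stood at 17.8 ± 0.908 against 4.10 ± 0.697 FPKM and did not pass (adjusted p = 0.0611), and Zic2 differed by −0.11 (adjusted p = 0.901). In all 135 genes passed, 114 up and 21 down, of which 20 had a value listed at 0. Quantile normalization moved the median of all genes from −0.14 to −0.02. The count was 61 without BDNF library 1, 75 without BDNF library 2, 28 with only these 2 groups in the fit, 33 among genes of the same span and 781 with the 3 libraries that stood apart left out. That last setting turned the majority, to 359 up and 422 down (46.0% up against 84.4%).

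Knockdown cultures asked which genes depend on Zic1 or Zic2. Zic2 was at 51.0 and 45.8 FPKM in the Zic2 knockdown, 138 and 99.4 in the control and 115 and 93.1 in the Zic1 knockdown. It was lower in both Zic2 knockdown libraries, with a difference of −1.26 (SE 0.29, n = 2 each), but did not pass limma's test (adjusted p = 0.32). Zic1 has no named value. A locus without a symbol on chromosome 9 (91255183 to 91260637), between Tbc1d2b and Plscr5, stood at 72.8 and 50.5 FPKM in the Zic1 knockdown, 204 and 165 in the Zic2 knockdown and 239.5 and 189.8 in the control. This locus was not part of the test. Zic2 differed by −0.18 in the Zic1 knockdown (adjusted p = 0.788).

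**Figure D4:**
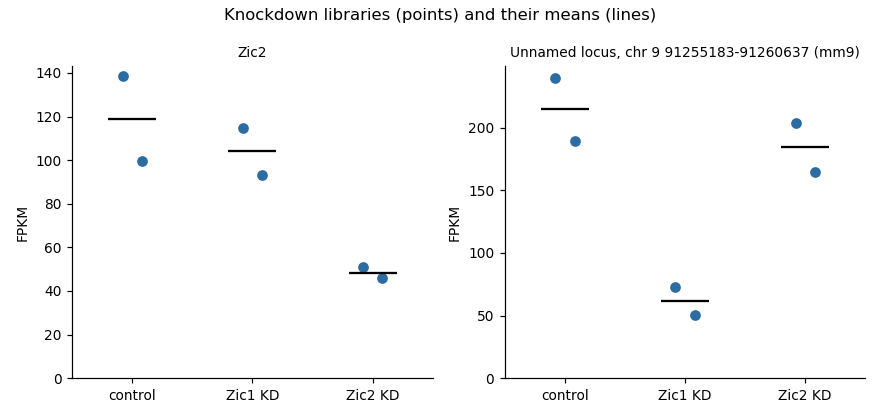
FPKM of Zic2 and of the unnamed chromosome 9 locus in each knockdown library (points) with group means (lines), n = 2 libraries per group. Zic2 was at 51.0 and 45.8 FPKM in the Zic2 knockdown against 138 and 99.4 in the control, and the unnamed locus at 72.8 and 50.5 in the Zic1 knockdown.

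With Zic1 knocked down 11 of 8685 genes passed limma's test, 5 up and 6 down. Pth2r rose from 0.230 ± 0.166 to 7.38 ± 1.24 FPKM (2.77, SE 0.27, n = 2 each, adjusted p = 0.0471). Mrps25, which overlaps another locus, fell from 96.7 ± 18.1 to 14.3 ± 0.910 FPKM (−2.67). The myelin gene Cldn11 fell to 6.57 ± 1.46 FPKM, 5.65-fold on the same scale. None of these passed with a pseudocount of 0.1 or no filter, nor Mrps25 under quantile normalization. The other named calls held values listed at 0: Fdft1 at 0 and 0 in the control against 17.9 and 18.7 FPKM, and Fbxl2 at 0 and 0 against 5.25 and 6.27. Kif20a was at 5.04 and 9.27 in the control against 0 and 0, and the mitochondrial translation gene Mrrf at 5.72 and 7.77 against 0 and 0. In all 8 of the 11 held such a value (72.7%, against 1.9% of genes tested, Fisher's exact test p = 2.48e-12). With limma 0 genes passed when genes with a value listed at 0 were left out, with 1340 at an unadjusted p under 0.05. Quantile normalization moved the median of all genes from −0.17 to 0.03 and gave 8 up and 4 down (66.7% up). The count was 19 without Zic1 knockdown library 1, 18 up and 1 down, and 30 with a replicate block, 10 up and 20 down. Without Zic1 knockdown library 2 it was 7 up and 2 down.

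Several lists lay below the control with Zic1 knocked down, with 1 member passing, Cldn11, which did not pass under quantile normalization. They were astrocytes (9 of 12 adjusted over the list alone, median −1.08, adjusted p = 4.55e-06, adjusted p = 0.356 with an estimated correlation) and the interferon response (9 of 10 adjusted over the list alone, median −1.20, adjusted p = 4.55e-06, adjusted p = 0.585 with an estimated correlation). Also lower were the cell cycle (0 of 26 adjusted over the list alone, median −1.13, adjusted p = 4.39e-05, adjusted p = 0.614 with an estimated correlation) and oligodendrocytes (2 of 11 adjusted over the list alone, adjusted p = 0.0115, adjusted p = 0.585 with an estimated correlation). Microglia (2 of 6 adjusted over the list alone, adjusted p = 0.0121, adjusted p = 0.614 with an estimated correlation) and fibroblasts (4 of 7 adjusted over the list alone, adjusted p = 0.0128, adjusted p = 0.585 with an estimated correlation) were lower too. Migration genes were higher (1 of 16 adjusted over the list alone, adjusted p = 0.0121, adjusted p = 0.585 with an estimated correlation). Gfap was at 7.52 ± 1.72 against 45.2 ± 0.621 FPKM, Gabrd at 1.87 ± 2.06 against 34.2 ± 11.7 and Top2a at 9.14 ± 9.34 against 86.0 ± 14.9, none of which passed (adjusted p = 0.093, 0.106 and 0.192).

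With Zic2 knocked down 8 genes passed limma's test, 6 up and 2 down. Klhl35 rose from 0.0604 ± 0.0182 to 18.5 ± 2.29 FPKM (n = 2 each, adjusted p = 0.0035). Olfr1033 fell from 14.5 ± 1.23 to 0.727 ± 0.160 (−3.17, adjusted p = 0.0203, not called with no filter). Fdft1 (0 and 0 in the control against 22.4 and 22.1) and the translation factor gene Eif2a (0 and 0 against 9.91 and 8.76) held values listed at 0, as did 5 of the 8 calls (62.5%, Fisher's exact test p = 1.32e-07). Without such genes 3 passed. The majority turned without control library 1, with 5 up and 11 down, and without control library 2, with 3 up and 8 down. The count was 16 without control library 1, 20 without Zic2 knockdown library 1 and 15 without library 2, and 9 with a replicate block. Astrocyte (0 of 12 adjusted over the list alone, median −0.47, adjusted p = 0.000324), fibroblast (3 of 7 adjusted over the list alone, adjusted p = 0.0041) and immediate early genes (0 of 24 adjusted over the list alone, adjusted p = 0.0385) lay lower, each with adjusted p = 0.487 with an estimated correlation. Migration genes lay higher (0 of 16 adjusted over the list alone, adjusted p = 0.0041, adjusted p = 0.487 with an estimated correlation). Mature granule neuron genes lay lower (0 of 17 adjusted over the list alone, adjusted p = 0.0211, adjusted p = 0.628 with an estimated correlation). Cell cycle (0 of 26), oligodendrocyte (1 of 11) and microglial genes (0 of 6) lay lower and synapse genes higher (2 of 16, all adjusted over the list alone). These 4 lists each had adjusted p = 0.0307, and adjusted p = 0.628 with an estimated correlation. Gabrd was at 7.53 ± 1.23 against 34.2 ± 11.7 FPKM (adjusted p = 0.377) and Stx1a at 51.4 ± 7.86 against 9.68 ± 0.367 (adjusted p = 0.182).

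Both knockdowns shared 2 calls in the same direction, Fdft1 and Mir3070b, which hold values listed at 0. Thus the excess over independent lists (0.0035 rises and 0.0014 falls) and simulated unchanged groups (0) cannot show a common response. Knockdown changes correlated at 0.475 across genes, and simulated unchanged groups gave 0.495 (0.437 to 0.571), since the control libraries are shared. The covariance was 0.199 against 0.143 simulated (0.122 to 0.182). With 1 control library for each knockdown it was 0.0916 or 0.0303, against −0.038 to 0.0492 and −0.046 to 0.0435 simulated, so 1 of the 2 splits lay outside the simulated range. Compared directly, the knockdowns differed for 12 genes, 5 higher and 7 lower with Zic1 knocked down. Olfr1033 was at 21.8 ± 3.39 against 0.727 ± 0.160 FPKM (3.71, n = 2 each, adjusted p = 0.0113) and Klhl35 at 0.0842 ± 0.0317 against 18.5 ± 2.29 (−4.17). Of the 12 calls 9 held a value listed at 0 (75.0%, Fisher's exact test p = 6.07e-14) and 2 passed without such genes. Quantile normalization moved the median of all genes from −0.22 to −0.02 and gave 15 up and 6 down (71.4% up). The count was 25 without Zic1 knockdown library 1 (20 up and 5 down) and 22 without Zic2 knockdown library 1 (1 up and 21 down). Without Zic1 knockdown library 2 it was 7 up and 5 down, and with a replicate block 31, 17 up and 14 down. Interferon genes were lower with Zic1 knocked down (4 of 10 adjusted over the list alone, adjusted p = 0.00626, adjusted p = 0.903 with an estimated correlation).

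Accessible chromatin was compared by the presence of peaks. Between P7 and P60, 9567 regions had a DNase peak in all 3 P7 libraries and no P60 library, 5138 in all P60 and no P7 library, and 43156 of 188326 merged regions in all 6. P7-only regions overlapped Neurod6 (chromosome 6, 55630745 to 55632580), whose transcript fell by 1.95 (adjusted p = 2.10e-06), or lay nearest Tbc1d22a (not called). P60-only regions on chromosome 4 (154734765 to 154736340) and chromosome 19 (9185862 to 9187451) overlapped the kinase gene Prkcz, whose transcript rose by 1.73, and Asrgl1, which rose by 1.15. At P14, 53.3% of P7-only regions (49.4% to 58.9% over libraries) and 56.7% of P60-only regions (47.6% to 72.2%) had a peak. Without P60 library 1 the total of 14705 age-specific regions was 22766, and the excess of P7-only regions was gone (11380 P7-only and 11386 P60-only). Lists of the same age overlapped with a Jaccard index of 0.524 against 0.399 between ages, a difference of 0.125 that 2 of 280 arrangements of the 9 libraries reached (exact permutation p = 0.00714). P60 lists went the other way, overlapping each other at 0.406 and P14 lists at 0.418.

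In culture 6293 regions were open at d0 only and 3638 at d7 only, with 48105 of 160099 open in all 6 libraries. Those at d0 only included regions near the potassium channel gene Kcnc4 (chromosome 3, 107233539 to 107234847) and the Wnt target Axin2 (chromosome 11, 108819225 to 108821264). Those at d7 only included regions in Usp29 (chromosome 7, 6818733 to 6819639) and near the junctophilin gene Jph3 (chromosome 8, 124223421 to 124224456). The total was 17987 without d0 library 1 and 18723 without d7 library 1. P7-only regions were open in 84.8% of cases at d0 (69.6% to 92.5%) and 52.9% at d7 (41.5% to 65.1%). P60-only regions were open in 18.3% at d0 (16.2% to 22.4%) and 49.4% at d7 (28.9% to 62.6%). Between d7 and BDNF 2032 regions were specific to d7 and 1785 to BDNF, with one in the collagen gene Col15a1 (chromosome 4, 47308305 to 47309255) at d7 only. Peaks of the BDNF libraries were narrower, with median widths of 544, 633 and 608 bp against 726, 884 and 1023 bp at d7. The total of 3817 was 2106 in the better-scoring part of each list and was 8044 when 50% of a region had to be covered. Lists of the same culture stage overlapped at 0.558 against 0.467 between stages, which 11 of 15400 arrangements reached (exact permutation p = 0.000714). The arrangements did not hold the replicate number fixed, although library 1 had the higher peak signal at d0, d3 and d7 (3.25, 3.29 and 4.26, against 0.93 to 1.39 in libraries 2 and 3). The d7 lists went the other way, overlapping each other at 0.482, d3 lists at 0.526 and d0 lists at 0.485.

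Zic binding was compared between the ages. Zic peaks were present in both P7 and no P60 libraries at 8098 regions, in both P60 and no P7 libraries at 6210, and in all 4 at 25172 of 66903. A P7-only site overlapped Frem2 (chromosome 3, 53315969 to 53319834), whose transcript fell by 2.17. Others lay nearest Neurl1b (chromosome 17, 26496665 to 26501762), which fell by 2.61, and Adcy8 (0.31, not called). A P60-only site overlapped Negr1 (chromosome 3, 156747019 to 156749402), which rose by 1.52. Others lay nearest Xkr6 (chromosome 14, 64442324 to 64446600) and Dnajc11, which fell by 0.96 and 0.29. H3K27ac was present at P7 only at 7193 regions and at P60 only at 6702, with 18822 of 58870 in all 4 libraries. P7-only regions overlapped Vipr1 (chromosome 9, 121572150 to 121581743), which fell by 1.17, or lay nearest Timm22 (not called). P60-only regions lay nearest Lhx2 (chromosome 2, 38233293 to 38236920), Gdf1 (not called) and Xkr6. The highest of the other splits of 4 libraries gave 1487 Zic and 1545 H3K27ac regions, and 2 libraries against 2 cannot give a p below 0.33. Without P7 Zic library 1 the Zic total of 14308 was 23443, and without P7 or P60 H3K27ac library 2 the H3K27ac total of 13895 was 27838 or 28071. The H3K27ac replicates differed in median peak width, 659 and 2373 bp at P7 and 867 and 2539 bp at P60.

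Age-specific Zic sites and accessible regions coincided in direction. Of P7-only Zic sites 2025 overlapped P7-only and 16 P60-only DNase regions, and of P60-only sites 12 and 1258 (Fisher's exact test, odds ratio 13300, p below what double precision holds). With H3K27ac in place of DNase the counts were 2628 and 19 against 15 and 1975 (odds ratio 18200). Sites bound at P7 only were accessible at P7 in 88.7% of cases and at P60 in 48.6%, and sites bound at P60 only in 30.4% and 69.0%. Some DNase peak lay at 99.5% of sites bound at both ages, 95.9% of P7-only and 86.5% of P60-only sites.

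Genes tied to 1 age-specific class, some also near shared regions, were compared by transcript. Near P7-only Zic sites 825 genes fell and 275 rose by P60, and near P60-only sites 390 fell and 582 rose (Fisher's exact test odds ratio 4.48, p = 5.15e-59). Near H3K27ac regions the counts were 903 and 252 against 384 and 629 (Fisher's exact test odds ratio 5.87, p = 1.16e-82), and near DNase regions 770 and 331 against 411 and 430 (Fisher's exact test odds ratio 2.43, p = 4.63e-21). Of called genes tied in this way to neither class 34.8%, 33.8% and 34.5% rose for DNase, Zic and H3K27ac.

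Genes near Zic sites were also examined in the knockdowns. The 7623 genes near sites bound at both ages had a median change of 0.03 in the Zic2 knockdown against −0.22 for other genes (camera adjusted p = 0.00151, adjusted p = 0.846 with an estimated correlation) and −0.15 against −0.38 in the Zic1 knockdown (adjusted p = 0.0951, adjusted p = 0.981 with an estimated correlation). Genes near P7-only (1874) or P60-only sites (1925) did not differ from the rest in either knockdown by more than chance, with adjusted p = 0.984 each. Of tested genes 90.7% lay near a Zic site, as did 9 of the 11 genes called in the Zic1 knockdown (Fisher's exact test p = 0.272) and 4 of the 8 in the Zic2 knockdown (Fisher's exact test p = 0.0038, and p = 0.0519 in the better-scoring part of each peak list by Fisher's exact test).

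Adult heart, kidney and liver, with 1 DNase library each, showed how far cerebellar regions are shared. Of 54830 regions open in all P60 libraries heart had a peak in 70.7% (70.3% to 71.0%), kidney in 69.2% (68.8% to 69.6%) and liver in 64.1% (63.7% to 64.5%). Of P7-only regions heart had a peak in 16.6% (15.9% to 17.4%), kidney in 17.5% and liver in 12.1%, and of P60-only regions in 34.3% (33.0% to 35.6%), 29.2% and 24.3%. The classes differ in median width, at 733 bp for P7-only, 941 bp for P60-only and 1647 bp for regions in all libraries.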

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

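Of the tests below, the prediction for the regrouping of RNA libraries, the exchange of DNase labels and the peak width test was written before its result was seen. The tests of values listed at 0, of DNase regrouping and of 2 kinds of DNase library were chosen only after the result was seen. Some rules for reading the last tests were also set after their values, as stated beside them.

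A difference between groups was found where tissue and culture were set side by side: 2296 genes changed differently from P7 to P60 than from d0 to d7. Of genes that passed in both with opposite signs, passed the test of the difference and had no value listed at 0, 80 rose in tissue and fell in culture and 208 fell in tissue and rose in culture. The larger side depends on scaling, as the opposite genes were 100 and 260 before the last 2 conditions and 179 and 158 under quantile normalization. The immediate early list also differed, with adjusted p = 0.0107 with an estimated correlation. Fos stood at 3.77 FPKM in P7 tissue and 245 in the d0 precursors taken from litters of that age, and at 9.36 and 10.9 in P60 tissue and d7 cultures.

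Of 100 groupings of the 12 libraries the real one ranked 1, with 2296 genes against 1067 for the highest other. The others mix ages or days, which widens the spread, so this cannot exclude chance. The difference was 3261 genes when the 3 culture libraries that stood apart were left out, so they are not its whole source. A hypothesis is that the isolation of the cells raised Fos, Fosb and Egr1 before RNA was taken at d0, which could place the fall of these genes in culture at its starting point. No group of the design separates isolation from the state of the precursors in tissue, so this hypothesis was not tested. The loss of other cell types in culture may add to the difference for oligodendrocyte and endothelial genes, which was not tested either.

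Between the knockdowns 12 genes differed, a difference between groups by the test itself, and values listed at 0 were weighed as a technical source of the knockdown calls. Leaving out genes with a value listed at 0 left 0 of 11 calls for Zic1, as this source needs, although Pth2r, Mrps25 and Cldn11 hold no such value, their log2 changes stay the same by construction (2.77, SE 0.27, for Pth2r), and they had shared an adjusted p of 0.0471 that rested on all 11 calls. It left 3 of 8 calls for Zic2 and 2 of 12 between the knockdowns, so such values are not the whole source there. Genes at 0 in 1 library and at 5 FPKM or more in another (120 of 8685) overlapped another locus in 72.5% of cases, against 10.9% of all others (Fisher's exact test p = 3.6e-55), so the assignment of fragments between overlapping loci might be involved. No biological explanation was tested, as no value in the design separates the effect of a hairpin from that of its target.

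DNase libraries P60 1 and P14 3 overlapped the lists of the other age more than those of their own, with a Jaccard index of 0.356 against 0.451 for P60 1 and 0.447 against 0.516 for P14 3. An exchange of their labels is excluded, because the share of P60-only minus P7-only regions with a peak in P60 1 was 10.3 points for Zic and 11.1 points for H3K27ac, against −33.3 and −32.5, and −26.0 and −25.3, in P14 1 and 2. With all peaks set to 150 bp the differences became −0.001 (0.137 and 0.138) for P60 1 and −0.031 (0.146 and 0.177) for P14 3. The rule written before would have counted any value below 0 against peak width, and was changed to undecided only after the value of −0.001 was seen; the single overlaps of P60 1 ran from 0.134 to 0.14 with its own age and from 0.135 to 0.141 with P14, while those of P14 3 stayed apart (0.142 to 0.151 and 0.168 to 0.186). Kinds of library were defined from the highest peak signal after the overlaps had been seen, and lists of different groups overlapped more within a kind in culture, where the kind is the same split as library 1 against 2 and 3 (0.563 and 0.465, a difference of 0.099, 27 arrangements, exact permutation p = 0.037) and in P14 with P60 (0.119, 9 arrangements, exact permutation p = 0.111), but not over all 9 cerebellum libraries (−0.025, 9 arrangements, exact permutation p = 0.667), so with a rule set after these values this explanation, which could apply in culture, stays undecided.

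For other counts the libraries allow only 10 splits, which are too few to decide. The real split ranked 1 for these, with the highest other split in brackets: 5767 genes for P60 against P7 (1), 4639 for P14 against P7 (2), 2593 for P60 against P14 (3), 3831 for d7 against d0 (3), 2747 for d3 against d0 (3) and 509 for d7 against d3 (68). For DNase regions it was 14705 for P7 and P60 (1147), 9931 for d0 and d7 (2485) and 3817 for d7 and BDNF (1444). Other splits gave more DNase regions than the labels for P14 and P60, 10543 against 6670, and for d3 and d7, 3549 against 2658.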

How the results depend on the processing

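No named gene turned its direction under any alternative, but the majority of calls turned in several comparisons. Of the values compared 155 stayed near the main one and 64 moved. Depth limits the low genes, and the knockdowns rest on 2 libraries per group. Where no construction is named below, the cause was not tested. Restricting the test to genes with the same span in every library, chosen after seeing the data, leaves fewer genes, and gave 2259 calls for P60 against P7, 1835 for P14 against P7, 1062 for P60 against P14, 1094 for d7 against d0, 714 for d3 against d0, 127 for d7 against d3, 33 for BDNF and 704 for the difference between tissue and culture. Leaving out d0 1, d3 3 and d7 3 together, also chosen later, gave 1513 for d7 against d3, 781 for BDNF and a correlation of tissue and culture of 0.594, and turned the majority for d3 against d0 (2069 up and 1857 down), d7 against d3 (728 and 785) and BDNF (359 and 422). Other alternatives chosen later were genes with no value listed at 0, which left 0 calls for Zic1, 3 for Zic2 and 2 between the knockdowns, the list tests with a block, the correlation without each library and the Zic-bound genes with an estimated correlation.

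A pseudocount of 0.1 gave 69 for BDNF, 5 for Zic1 and a correlation of 0.532. No filter gave 338 for BDNF, 6 for Zic1, 7 between the knockdowns and a correlation of 0.519. Quantile normalization gave 21 between the knockdowns, and turned the majority for P60 against P7, P14 against P7, d7 against d0, Zic1, between the knockdowns and for the difference between tissue and culture. Without the filter it turned for Zic1 (4 up and 2 down) and between the knockdowns (4 and 3), and among genes of the same span between the knockdowns (8 and 7). Fits of the compared groups only, which hold fewer libraries, gave 202 for d7 against d3, 28 for BDNF and 7 for Zic1. Leaving out each library in turn gave 223 (without d3 2) to 540 (without d7 3) for d7 against d3, 61 to 145 for BDNF, 9 to 19 for Zic1, 11 to 20 for Zic2, 12 to 25 between the knockdowns and a correlation of 0.526 to 0.589. The majority turned without d3 3 for d3 against d0 (1272 up and 1199 down), without Zic1 knockdown 1 (18 and 1) or 2 (7 and 2) for Zic1, without control 1 (5 and 11) or 2 (3 and 8) for Zic2, and without Zic1 knockdown 1 (20 and 5) or 2 (7 and 5) between the knockdowns. A lone library left in a group was assumed to vary like the others.

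The replicate block gave 30 for Zic1 and 31 between the knockdowns, where it turned the majority (17 up and 14 down). Counts with this pairing were 5692 for P60 against P7, 4502 for P14 against P7, 2387 for P60 against P14, 3834 for d7 against d0, 455 for d7 against d3, 152 for BDNF, 9 for Zic2 and 2086 for the difference between tissue and culture. For BDNF the block gave 100 up and 52 down, and it ended the calls of 6 named genes for d7 against d3, 4 for BDNF, 2 for P60 against P14 and 1 for d3 against d0. The most such losses under any alternative were 18 for d7 against d3 and 12 for BDNF (compared groups only), 14 for P60 against P14 (without P60 3), 8 for d3 against d0 (without d3 2), 6 for Zic1 (such as without control 2) and 5 for d7 against d0 (without d0 3). Deviations of libraries with the same number correlated at −0.006, 0.058 and −0.06 for P60 with P7, −0.061, −0.071 and 0.145 for P14 with P7, −0.095, 0.187 and 0.081 for P60 with P14, 0.067, 0.04 and 0.016 for d7 with d0, and −0.053, −0.106 and −0.151 for d7 with d3.

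With an estimated correlation 6 of 85 list calls held, and of Zic-bound gene sets 0 of 1. Regions overlapping the gene locus only gave 2 Zic-bound calls, and the better-scoring part of each peak list gave 2, none of which held with an estimated correlation (adjusted p = 0.807 each and adjusted p = 0.711 each). That part, which holds fewer peaks, gave 2106 DNase regions for d7 and BDNF, 7155 Zic and 7605 H3K27ac regions, 68.7% of P60 regions in kidney and 61.8% in liver. Coverage of 50% gave 8044 DNase regions for d7 and BDNF and 6367 for H3K27ac. Leaving out a library asks fewer lists to concur: DNase regions for P7 and P60 numbered 17865 to 22766 (without P60 1), for d0 and d7 10891 to 18723 (without d7 1), for d7 and BDNF 6009 to 7709, Zic regions 20154 to 23443 (without P7 1) and H3K27ac regions 20054 to 28071 (without P60 2).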

Other observations

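Zic sites were also read in cultured granule neurons. Sites bound at P7 only had a DNase peak in 84.5% of cases at d0, 88.0% at d3 and 78.8% at d7, and sites bound at P60 only in 47.7% at d7 against 69.0% in P60 cerebellum. H3K27ac covered 51.5% of P7-only Zic sites at P7 and 7.5% at P60, and 17.8% and 72.2% of P60-only Zic sites. With BDNF 45.4% of P7-only DNase regions (38.3% to 48.9%) and 42.2% of P60-only regions (31.1% to 47.9%) had a peak. These shares come from lists of equal length with narrower peaks in the BDNF libraries, and no test was made of them.

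Some gene lists held members that passed although the list was not called. Microglial markers fell for 10 of 13 genes and rose for 1 by P14 (adjusted p = 0.101 for the list), and astrocyte markers rose for 7 of 12 and fell for 4 (adjusted p = 0.149). None of 10 interferon genes passed limma's test at d3 against d0 (list adjusted p = 0.364), while 7 rose from d3 to d7. Fibroblast-type genes fell for 4 of 9 by d3 (adjusted p = 0.145), with the pericyte gene Rgs5 at −4.39. Gfap rose from 50.5 ± 14.1 at d0 to 355 ± 188 FPKM at d3 (n = 3 each).

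The unnamed locus on chromosome 9 (91255183 to 91260637) stood at 309, 367 and 250.04 FPKM at P7, 272, 307 and 292 at P14, and 189 and 178 in the 2 P60 libraries that list it. In culture it stood at 443, 481 and 442 FPKM at d0, 411, 371 and 458 at d3, 414, 408 and 199 at d7 and 247 and 245 with BDNF. It was in no test. The neighbouring unnamed locus (91263810 to 91284186) stood at 18.1 and 12.5 FPKM in the Zic1 knockdown, 32.9 and 28.6 in the Zic2 knockdown and 21.0 and 21.1 in the control.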
